A study of Drosophila melanogaster with 3 samples.

How the data were processed

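ORC2 ChIP DNA and input DNA from hand-sorted egg chambers were hybridised to Agilent tiling arrays, 1 array for each of 3 groups: TOW stage 10, MOD stage 10 and TOW stage 9/10. Per the labels' protocols, batches of 300 egg chambers were fixed in 2% formaldehyde and 4 batches were pooled for a sample. ChIP DNA was labelled with Cy5 (red) and input with Cy3 (green), per the labels, and no array had its dyes swapped. The groups were taken from the sample titles.

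The scanner files hold intensity values that the authors obtained with Agilent Feature Extraction 10.1.1.1 under the protocol CGH-v4_10_Apr08, per the file headers. The processed intensities were background-subtracted, spatially detrended and dye-normalized by that software, per the file headers, with dye normalization given as selection code 6 and correction code 0, which the headers do not spell out. Low signals were replaced by surrogates in these columns. The deposited value tables hold the log10 ratio of Cy5 over Cy3; set against the log ratios of the scanner files, they differed by 0 on all features, so their direction and scale are settled and they are not centred. The authors also deposited MA2C-normalized values for the stage 10 arrays, which are log2 ratios by their column name; the 116199 listed values had a mean of 0 and an SD of 1.00 on each array, so these deposited values were read as a score in array SDs. Their MA2C version and settings are not given in the sources used here, and they correlated with the scanner log ratios with an r of 0.71 for TOW and 0.80 for MOD. Flag columns of the deposited files mark signals as well above background, saturated or outlying.

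Probe positions on flybase dmel5.1 were read from the stage 10 files, per the file headers and probe columns. The TOW stage 9/10 file names the dm3 build in its header and holds no probe positions as read here, so its probes were placed by the number in their names. This placement was checked: 116199 probe names were shared between the platforms and all 116199 had the same sequence. All 68502 pairs of probes from different platforms that were placed within 30 bp of each other also had the sequence overlap their numbers give. On that array 25 probes were not placed. No genome was used, and the gene table at hand is on Release 6, so no gene was assigned to a position. For this reason the planned ORC2 level at amplicon loci, promoter levels and gene groups at promoters were not run, and regions are given by position in place of gene names.

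Control spots and outlier-flagged features were left out (76, 134 and 977 probes flagged, in the order TOW stage 10, MOD stage 10, TOW stage 9/10). The log2 ratio of processed red over green signal was centred on each array's median, without loess or quantile normalization. Median background-subtracted ChIP signals were 115, 219 and 1328, and input signals 380, 373 and 1990. A smoothed value is the median over probes within 1000 bp either side, with at least 4 probes. The threshold of an array was the smallest smoothed value at which probes at or below its negative numbered at most 5% of those at or above it, a mirror share that describes the asymmetry of 1 array and is no test between samples. Passing probes up to 1000 bp apart were joined, and a region needed at least 3. Calling was tested on simulated arrays with the real probe positions, correlated noise and 200 planted regions of 3 kb in each.

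Broad domains were defined after the data were seen as intervals where the sliding median over 5000 bp either side (at least 8 probes) was at least 1, joined within 10000 bp, with a highest value of at least 1.5. Without the last condition there were 51 intervals in TOW stage 10, 18 in MOD stage 10 and 26 in TOW stage 9/10, and with it 8, 6 and 1. Each union domain was measured over 10 kb around its middle and set against 10000 random windows of that width on the same array. Sharp-edged runs were also chosen after the data were seen, as at least 3 probes bounded on both sides by steps of at least 3 (log2) in TOW stage 10. Correlations were computed across bins of 2 kb, and overlaps of at least 1 bp were set beside 100 random placements. Input was the log2 processed green signal centred on the array median.

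The named regions followed a rule fixed before the data were examined: the 10 regions with the highest smoothed peak of each array, and the 10 largest differences in each direction between TOW and MOD at stage 10 among regions enriched in at least 1 of these arrays. Chromosome arms and scaffolds were fixed as probe groups. Alternatives were normexp correction (offset 50), the MA2C values, the deposited value tables, centring within 20 bins of probe GC content, division by the array's robust SD, a filter on probes well above background, other smoothing widths, thresholds, window widths and bins, and a thinned dense array. Differences between groups were not tested, since each group has 1 array. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.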

Results

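ORC2, a subunit of the origin recognition complex that marks sites where DNA replication can start, was mapped by chromatin immunoprecipitation (ChIP) on tiling arrays in egg chambers of Drosophila melanogaster, the units of the ovary in which follicle cells surround a developing germline cyst. The series held 3 arrays in 3 groups, 1 array per group. The OregonR^TOW and OregonR^MOD strains, called TOW and MOD here, were each measured at stage 10, and TOW was also measured in a sample of stages 9 and 10 (TOW stage 9/10). Each array carried ORC2 ChIP DNA in the red channel and input DNA in the green channel. After control spots and outliers were left out, 241393 probes were used on the TOW stage 10 array, 241335 on the MOD stage 10 array and 949377 on the denser TOW stage 9/10 array, with a median spacing of 470, 470 and 110 bp. ChIP signal was well above background for 85.3% of probes on the TOW stage 10 array, 93.4% on the MOD stage 10 array and 97.7% on the TOW stage 9/10 array. Input signal was well above background for 97.7%, 98.0% and 98.3% of probes in the same order, and no probe was saturated. The probe log2 ratios of ChIP over input had a robust SD of 0.60, 0.40 and 0.36. With 1 array per group no difference between groups has a replicate check, no p-value is given, and the number of arrays limits the precision; SDs printed below are spreads over probes, which are not replicates. Coordinates are those of the stage 10 files (flybase dmel5.1), and no gene is named because no annotation on this build was used.

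The first question was where ORC2 was enriched in each sample. The tallest signals that spread over many kilobases were on arms 3L, 2L and X. On both stage 10 arrays a region on 3L reached the highest smoothed log2 ratio of this kind, 4.42 in TOW (8719911 to 8742131, 22.2 kb) and 4.34 in MOD (8712561 to 8742131, 29.6 kb). Means over the TOW region were 2.79 in TOW stage 10, 2.85 in MOD stage 10 and 0.42 in TOW stage 9/10. A region on 2L (13412041 to 13419611 in TOW stage 10) was among the 10 tallest of every array, with peaks of 2.74 in TOW stage 10, 2.68 in MOD stage 10 and 2.03 in TOW stage 9/10. The X region from 8360921 to 8386441 peaked at 2.55 in TOW stage 10. In MOD it was called as 2 regions, with peaks of 2.40 and 2.25. The top 10 of TOW stage 10 also held 2 regions on U, the collection of unplaced sequence, with peaks of 2.45 and 2.33. All U probes of that array had a median of 1.36, with 62.4% of input and 54.1% of ChIP signals well above background. These 2 peaks thus stand on a raised level and are not read as ORC2 binding. The tallest region of TOW stage 9/10 lay on 2L (158871 to 163041), with a peak of 2.47 and a mean of 1.64 on that array, against means of 0.29 in TOW stage 10 and 0.98 in MOD stage 10. The next was on 2L as well (3537671 to 3540991), with means of 1.71 in TOW stage 9/10, 1.55 in MOD stage 10 and 0.30 in TOW stage 10. On 3R (19025151 to 19028101) the means were 1.65 in TOW stage 9/10, 0.85 in MOD stage 10 and 0.00 in TOW stage 10.

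In total 1778 regions were called in TOW stage 10 at a smoothed log2 ratio of at least 0.81, 884 in MOD stage 10 at 0.72 and 1171 in TOW stage 9/10 at 0.76. They covered 2998, 1560 and 2127 kb, with median widths of 1411, 1391 and 1501 bp. Few were tall, with 23, 11 and 8 regions reaching a peak of 2. On simulated arrays with planted regions of 3 kb, the same thresholds recovered 64%, 80% and 90% of regions at a log2 ratio of 1 and at least 98% at 2. Outside the planted regions, 367 regions were called on the simulated TOW stage 10 array, 63 on MOD and 8 on TOW stage 9/10. The counts depend strongly on the threshold and the signal used: a mirror share of 1% in place of 5% left 5, 3 and 74 regions, and normexp-corrected signals gave 6066, 3 and 1150. The TOW stage 10 count fell below the 884 reported for MOD with the uncentred deposited tables and with probes well above background in both channels. MOD counts under these same settings are not given, so the order of the arrays within each setting is not shown.

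The design asked for ORC2 levels at the known amplicons, loci that follicle cells replicate repeatedly to raise the copy number of eggshell and other genes. These loci were fixed beforehand by genes and could not be placed on this build, so broad domains were defined after the data were seen. There were 8 such domains over the 3 arrays, and each was measured over 10 kb around its middle. The 3L domain from 8713061 to 8741781 had a mean log2 ratio of 3.46 in TOW stage 10 (SD 0.65 over 21 probes) and 3.60 in MOD stage 10 (SD 0.52, 21 probes). The X domain from 8360511 to 8386441 had means of 2.29 (SD 0.25) and 2.12 (SD 0.26). At 3L 2265951 to 2284771 the means were 1.83 in TOW and 1.81 in MOD, at 2L 9540111 to 9551521 they were 1.71 and 1.58, and at 2L 13410481 to 13420571 they were 1.56 and 1.41. All domains were chosen for their height on these arrays, so their rank among random windows of the stage 10 arrays restates the choice and is not given.

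**Figure D1:**
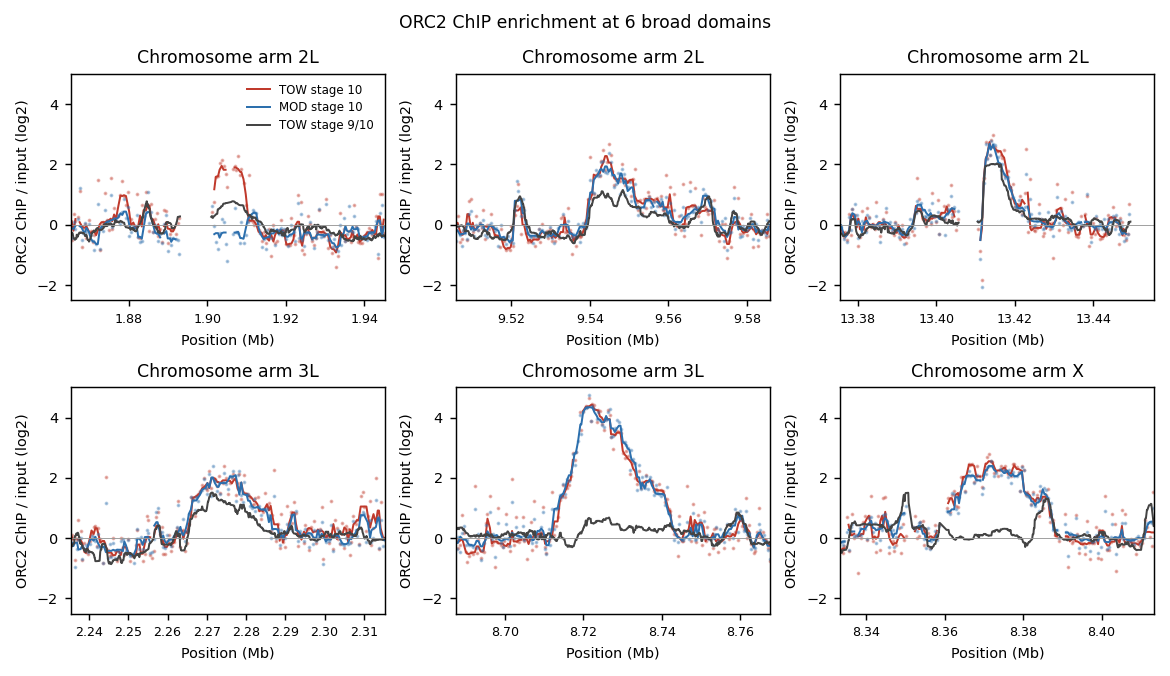
ORC2 ChIP over input (log2, vertical axis) against position in Mb (flybase dmel5.1, horizontal axis) at the 6 broad domains that hold no sharp-edged run and whose probes were mostly above background; lines are 2 kb sliding medians for TOW stage 10, MOD stage 10 and TOW stage 9/10, points are single probes of the stage 10 arrays, and lines break where probes lie more than 2 kb apart. The TOW and MOD lines lie close together in 5 panels and apart at 2L 1901181 to 1909301, where the 10 kb means were 1.58 and -0.25.

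The remaining domains each had a limit of their own. The 2L domain from 1901181 to 1909301 was high in TOW stage 10 and not in MOD stage 10 and is described with the strain comparison. The domain on 2R (18009191 to 18014761) was made by a sharp-edged run of probes, described below. The domain at the tip of 3L (20861 to 43051) had means of 1.49 in TOW and 1.00 in MOD, but only 7 of its 18 probes had input well above background in TOW and 5 in MOD, so these ratios compare signals near background. In TOW stage 9/10, 5 of the 8 domains lay in the upper 2.5% of random windows. The number was 3 with windows of 50 kb and 1 when the highest smoothed value in the window was used. The domain at 2L 13410481 to 13420571, among the 5, also met the domain rule on this array, so its rank here restates the choice.

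The strain comparison set TOW against MOD at stage 10 on arrays of the same design. The 2L domain from 1901181 to 1909301 was enriched in TOW, while MOD lay below its array median there. Over its 10 kb window the mean log2 ratio was 1.58 in TOW (SD 0.53, 17 probes, a 3.00-fold ratio) and -0.25 in MOD (SD 0.47, 17 probes). The difference of 1.84 (SD 0.72 over 17 probe differences) was reached by 1 of 10000 random windows, a description only, since the domain was chosen for its height in TOW. In TOW stage 9/10 the mean was 0.57, as high as or higher than in all but 115 of 10000 random windows. All 17 probes had ChIP and input signal well above background in TOW, and 16 of 17 did in MOD for each channel. The difference kept its sign under every alternative run, with 1.80 to 1.96 for the settings that stay on the log2 scale of the 10 kb mean, and it was 0.45 over 50 kb. The 3L tip, near background, and the 2R domain, with its sharp-edged run, differed by 0.49 and 1.42. At the 5 other measured domains the strains lay close together on the log2 scale, with TOW minus MOD of -0.15 at 3L 8713061 to 8741781, 0.18 on X, 0.02 at 3L 2265951 to 2284771, 0.12 at 2L 9540111 to 9551521 and 0.15 at 2L 13410481 to 13420571. With normexp, 4 of these 5 differences were 0.72 to 0.98 and that at 3L 8713061 to 8741781 was -0.27. Divided by each array's robust SD, which is wider in TOW, all 5 were negative, from -3.21 at 3L 8713061 to 8741781 to -0.91 at 2L 13410481 to 13420571.

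**Figure D2:**
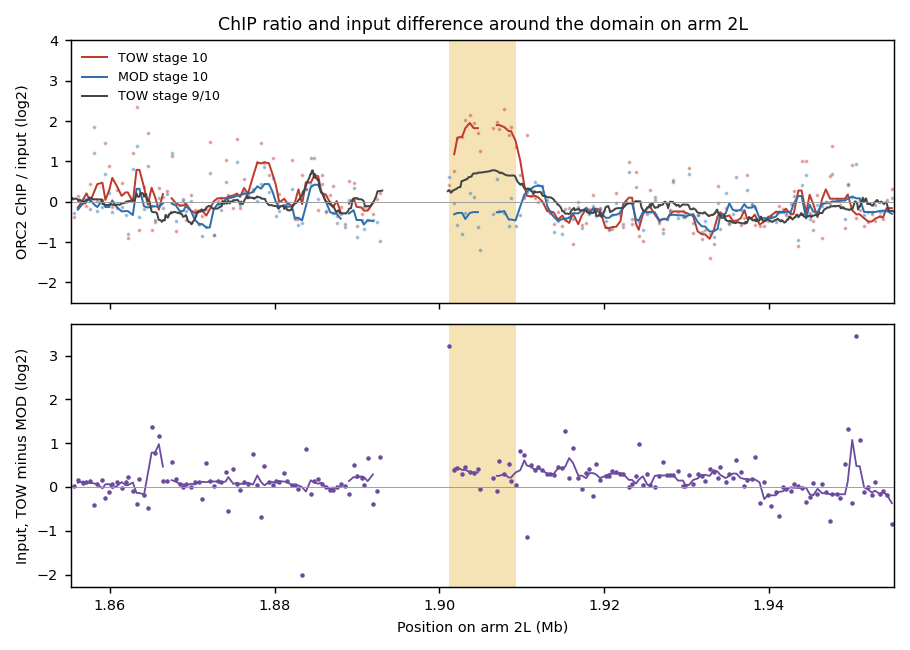
The upper panel plots ORC2 ChIP over input (log2) and the lower panel input signal, TOW minus MOD at stage 10 (log2), against position on arm 2L in Mb (flybase dmel5.1), with probes as points, 2 kb sliding medians as lines and the domain from 1901181 to 1909301 shaded. TOW stage 10 rises inside the shaded domain (10 kb mean 1.58) while MOD does not (-0.25), and the input difference there has a median of 0.34, with a single probe at the left edge far above the rest.

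Input DNA carries copy number, so input signal was compared on the same probes. At 2L 1901181 to 1909301 the input was 0.49 higher in TOW than in MOD (SD 0.74, 17 probes), which 31 of 10000 random windows reached. The median of the probe differences was 0.34, and the mean was 0.17 with probes well above background in both channels only. The input differed by 0.41 at the 3L tip, near background, which 80 of 10000 random windows reached, and by -0.17 at the 2R domain. At the 5 other measured domains the input differed by 0.07 to 0.18. Between TOW stage 10 and TOW stage 9/10, on the probes that both platforms share, input was higher at stage 10 by 1.498 at 3L 8713061 to 8741781 (SD 0.47, 8 probes), by 0.83 at the X domain (SD 0.70, 8 probes) and by 0.74 at 2L 13410481 to 13420571 (SD 0.58, 10 probes). Of 10000 random windows, 2, 59 and 113 had a difference as high. The difference was 0.46 at 2L 9540111 to 9551521 and 0.37 at 3L 2265951 to 2284771, which 784 and 1261 random windows reached. It was -0.11 at the 2R domain and -0.66 at the 3L tip. At 2L 1901181 to 1909301 this difference was 0.18 (SD 0.62, 9 probes), which 3030 random windows reached. These inputs were read on different platforms, so stage, platform and array cannot be told apart. Random windows do not remove a platform effect on so few probes, and the stage differences are not read as copy number.

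Beyond the domains, 2280 regions were enriched in TOW, in MOD or in both at stage 10. Of these, 377 were called in both arrays, 1398 in TOW only and 505 in MOD only, from separate calls with different thresholds and spreads. Of the 2280 regions, 1717 were higher in TOW and 563 higher in MOD. The median difference was 0.43, and 0.27 in regions called in both arrays. A difference of more than 1 was seen for 16 regions higher in TOW and 8 higher in MOD. This split was 77 to 454 after division by the robust SD, 28 to 436 with the deposited MA2C values and 226 to 0 with normexp. The robust SD and MA2C scalings count differences in units of each array's own SD, which is wider in TOW, so those splits follow from the scaling. The 10 regions with the largest differences higher in TOW included 2 regions inside the 2L domain (1901791 to 1904731, difference 1.97; 1906961 to 1909871, difference 1.86) and a region on 3R from 10323191 to 10325051 (difference 1.45, SD 1.65 over 5 probes). The top of that list, on 2R from 10761641 to 10763131, differed by 2.35, but only 1 of its 4 probes was well above background in TOW and the input difference, TOW minus MOD, was -5.89. Another 4 were the sharp-edged runs, and the last 2 lay on 2RHet and U, where the difference changed sign with normexp.

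Regions higher in MOD were narrow. On 2L from 3537391 to 3540691 the mean log2 ratio was 1.44 in MOD and 0.33 in TOW, a difference of -1.10 (SD 0.73, 8 probes). At 2L 160421 to 161801 the means were 1.52 and 0.49, and at 2R 12017051 to 12018521 they were 1.28 and 0.21. The same places had means of 1.69, 2.36 and 1.63 in TOW stage 9/10. Of the 10 regions named as higher in MOD, 7 changed sign with normexp, among them the region on 2R just named. The first of that list, X 896911 to 897791, differed by -1.42, but none of its 3 probes had input well above background in MOD and its input was 3.48 higher in TOW. At 2L 22709071 to 22712471, with a difference of -1.02, 2 of 8 probes were above background in MOD.

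At 4 places, chosen after the data were seen, there were runs of probes that rose and fell between neighbouring probes on both stage 10 arrays and not on the TOW stage 9/10 array. On X from 2684351 to 2687231 the mean log2 ratio of 7 probes was 8.88 in TOW and 5.82 in MOD, against -0.01 in TOW stage 9/10. On 2R from 18009591 to 18014761 the means of 12 probes were 7.69, 5.21 and -0.17. The run on 3R from 19858101 to 19859521 had means of 5.03, 3.49 and -0.39, and the run on X from 2139641 to 2140551 had means of 4.77, 3.20 and -0.36. A single probe at X 2690411 had values of 8.24 in TOW and 5.34 in MOD. In units of array SDs, which are wider in TOW, TOW lay below MOD at all 4 regions that hold these runs with the MA2C values and at 3 of them with the robust SD.

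**Figure D3:**
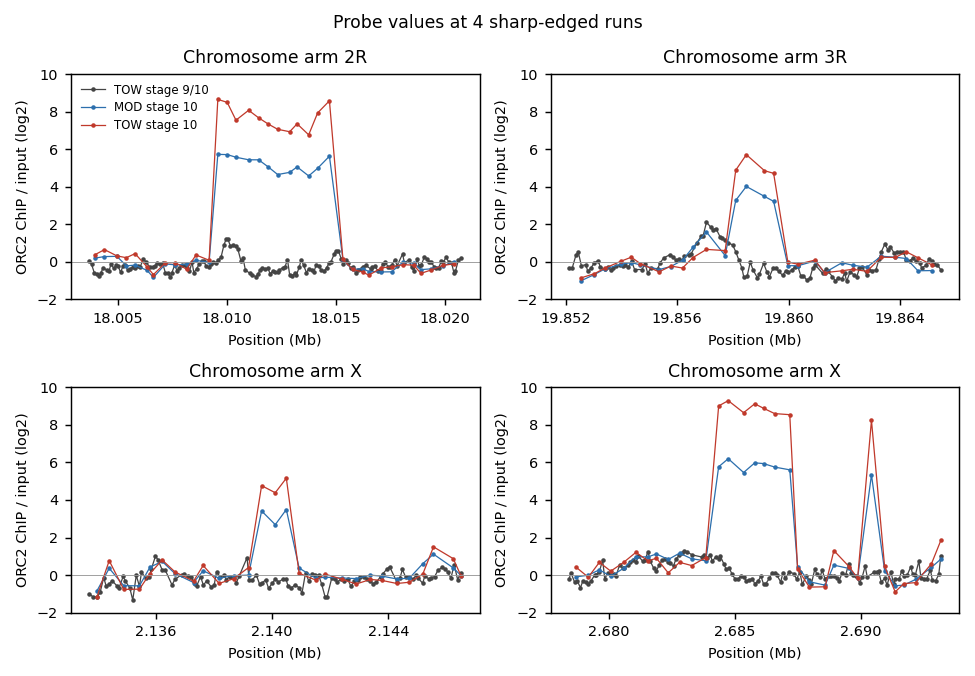
Probe values of ORC2 ChIP over input (log2, vertical axis) against position in Mb (flybase dmel5.1, horizontal axis) at the 4 sharp-edged runs, with lines joining neighbouring probes of TOW stage 10, MOD stage 10 and TOW stage 9/10. Both stage 10 arrays step up and down at the same probes, with run means in TOW from 4.77 to 8.88, while TOW stage 9/10 has run means from -0.39 to -0.01; the regions that hold the runs lie lower in TOW than in MOD at all 4 places with the MA2C values and at 3 with the robust SD, both in array SDs.

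The stage comparison set TOW stage 10 against TOW stage 9/10. The broad domains differed in how much of their stage 10 level was seen in stage 9/10. At 2L 13410481 to 13420571 the TOW means were 1.56 at stage 10 and 1.28 in stage 9/10, and at 3L 2265951 to 2284771 they were 1.83 and 1.17. By contrast, the 3L domain from 8713061 to 8741781 had 3.46 against 0.48, which 210 of 10000 random windows of stage 9/10 reached, and the X domain had 2.29 against 0.16, which 1759 reached. The 2L domain from 9540111 to 9551521 lay between, with 1.71 and 0.87. Across 56357 bins of 2 kb, the arrays correlated with a Pearson r of 0.45 and a Spearman rho of 0.46; bins are not independent replicates. MOD stage 10 correlated more strongly with TOW stage 9/10 (r 0.60, rho 0.52), and the 2 stage 10 arrays correlated with r 0.82 and rho 0.82. The stage 10 arrays carry the same probes, and their probe values minus the 2 kb median correlated with r 0.83. The 0.82 is therefore not read as likeness of ORC2 profiles alone. In 10 kb bins r was 0.76 between the stage 10 arrays. With TOW stage 9/10 it was 0.68 for MOD stage 10 and 0.52 for TOW stage 10. Stage 9/10 lay on another platform and each sample has 1 array, so stage, platform and array cannot be told apart. With normexp, r was 0.32 for TOW stage 10, 0.54 for MOD stage 10 with TOW stage 9/10, and 0.41 between the stage 10 arrays.

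Over all called regions, those of MOD stage 10 were shared more with TOW stage 9/10 than with TOW stage 10. Of the 884 MOD regions, 551 (62.3%) overlapped a region of TOW stage 9/10 and 379 (42.9%) a region of TOW stage 10, whereas random placement gave means of 3.41% and 5.56%. Of the 1171 regions of TOW stage 9/10, 207 (17.7%) overlapped a region of TOW stage 10, with 5.28% at random, and 545 (46.5%) a region of MOD stage 10, with 2.67% at random. The share of TOW stage 9/10 regions overlapping TOW stage 10 was 69.0% with normexp, 8.10% with the deposited tables and 7.92% with probes well above background, and the share of MOD regions overlapping TOW stage 10 was 28.0% and 24.0% with the latter settings. Regions called in all arrays were fewer, as 171 of the MOD regions (19.3%) overlapped regions of both TOW arrays. Of the 10 tallest regions of TOW stage 9/10, 9 overlapped a region of MOD and 3 a region of TOW stage 10. The order was the other way for the 10 tallest MOD regions, of which 9 overlapped a region of TOW stage 10 and 6 a region of TOW stage 9/10. All 10 of the tallest TOW stage 10 regions overlapped a region of MOD, and 5 a region of TOW stage 9/10. The tallest regions of both stage 10 arrays include the 4 sharp-edged runs, which were chosen for their height in TOW stage 10. Runs of this kind were not seen in TOW stage 9/10. The order among the tallest MOD and TOW stage 10 regions thus restates that choice in part, and counts without the runs are not given. Over the 1159 regions of TOW stage 9/10 that hold probes of both stage 10 arrays, the ratio was lower in TOW than in MOD in 897 (77.4%), with means of 0.67 in TOW and 0.86 in MOD. With normexp these means were 0.62 and 0.18, the MOD array had only 3 regions, and none overlapped TOW stage 9/10.

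Among chromosome arms, the small chromosome 4 had the highest median log2 ratio of the main chromosomes on every array, with 0.06 in TOW stage 10, 0.22 in MOD stage 10 and 0.38 in TOW stage 9/10. The 5 large arms had medians between -0.05 and 0.04. Heterochromatin scaffolds had higher medians than the 5 large arms, as on 3RHet with 0.78, 0.50 and 0.42 and on 2RHet with 0.37, 0.32 and 0.19. Input was well above background for 77.5%, 86.5% and 85.1% of 3RHet probes and for 88.3%, 91.6% and 93.2% of 2RHet probes. For ChIP in TOW stage 10 these shares were 64.4% and 71.7%. In TOW stage 9/10 chromosome 4 lay above 2RHet, 3LHet, XHet and 2LHet. Scaffolds of YHet reached 1.55, 0.96 and 0.50, but only 32.3%, 31.6% and 31.3% of their probes had input well above background. These ratios compare signals near background and are not read as ORC2 binding. Regions were called there all the same, as from 139341 to 150101 in MOD stage 10, with a peak of 1.32. Probes of U had medians of 1.36, 0.80 and 0.41, with 62.4%, 67.4% and 71.1% of input signals well above background. In TOW stage 10 the medians of the scaffold groups and U rose as the share of input well above background fell. They ran from XHet (0.31 at 93.8%) to YHet (1.55 at 32.3%), and on the other arrays this order was not strict. The higher scaffold medians are therefore not read as more ORC2 binding.

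**Figure D4:**
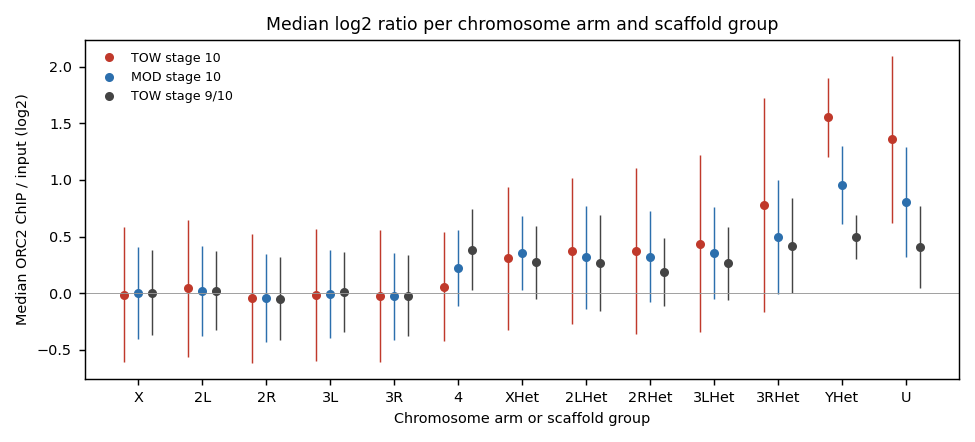
Median ORC2 ChIP over input (log2, vertical axis) of the probes of each chromosome arm or scaffold group (horizontal axis) on the 3 arrays; points are medians and bars reach 1 robust SD of the probes either side. The 5 large arms lie near 0, chromosome 4 lies between 0.06 and 0.38, and YHet lies highest on each array (1.55, 0.96 and 0.50), where most probes were not well above background.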

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

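All tests of explanations below, and the choice of the 4 sharp-edged runs and the broad domains, were made after the result was seen. The results here were singled out because samples had ORC2 ratios on opposite sides of the array median, except the likeness of TOW stage 9/10 to MOD, which was picked from the correlations, and none of these differences was tested, since each group has 1 array.

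At stage 10 the strains had opposite signs at the 2L domain from 1901181 to 1909301, where TOW minus MOD was 1.84 (1.58 in TOW and -0.25 in MOD). The regions inside it, 1901791 to 1904731 and 1906961 to 1909871, differed by 1.97 and 1.86, and they are the same signal. Opposite signs were also seen on 2R from 10761641 to 10763131 (2.35), on X from 896911 to 897791 (-1.42) and on 3R from 19025801 to 19027561 (-0.99, with -0.03 in TOW, 0.95 in MOD and 2.15 in TOW stage 9/10, but a difference of 0.015 with normexp); the difference was not tested at any of them. On 2R and X the sample with the higher ratio had few or no probes with input well above background.

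Weaker enrichment on the whole MOD array was weighed as an explanation of the 2L domain. TOW minus MOD averaged 0.066 ± 0.131 (SD, n = 5 domains) at the other measured domains, which argues against it. Left out were the 3L tip (0.49, near background) and the 2R domain (1.42, a sharp-edged run). Over the 2280 regions enriched in either array, 1398 of them called in TOW only, the median difference was 0.43, and 0.27 in regions called in both. This lean toward TOW lies below the 1.84 at the 2L domain, but that domain has the largest difference of those without a sharp-edged run. Most of the 2280 regions also entered through TOW only, so this comparison does not bear on a weaker MOD array. With normexp the average at the 5 domains was 0.62. Scaling TOW by the ratio of the arrays at those domains would still give MOD 1.17 at the 2L domain, against -0.18 measured. Sequence missing from the MOD sample, or not hybridising in it, is argued against by the 94.1% of the 17 probes that had MOD input well above background. A higher copy number in all cells of the TOW sample would be divided out by the input. TOW minus MOD of the ratio was still 1.96 without the probes whose input differed by more than 2. Input came from whole egg chambers and was 0.49 higher in TOW here, so this cannot decide on a copy gain in only some of the cells. A difference in ORC2 binding between the strains may underlie the domain and stays open as a hypothesis, since strain and array cannot be told apart with 1 array each. The domain also borders a stretch without probes, so its left end was not measured.

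Between TOW stage 10 and TOW stage 9/10 the signs differed at the 2R domain from 18009191 to 18014761, with 4.32 at stage 10 and -0.20 in stage 9/10, and at the runs it belongs with. On TOW stage 9/10 the runs had means of -0.17 (2R from 18009591), -0.39 (3R from 19858101), -0.36 (X from 2139641) and -0.0057 (X from 2684351), against 7.69, 5.03, 4.77 and 8.88 on TOW stage 10.

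Loss of input signal does not account for the runs, since the lowest mean input over them was 0.24 above the array median. Fragments of cloned or amplified DNA in the ChIP samples might give such edges, and the steps at the run ends were at least 83.8% of the run height. Other regions reached 237.9% of their height, and 96 of 180 on TOW but only 1 of 27 on MOD stepped as steeply as the lowest run (medians on MOD 45.7% for other regions and 88.0% for the runs). Over the whole array, however, 2.5% of neighbouring probe pairs differ by at least 2.05 on TOW and 1.32 on MOD. This is 126.5% and 79.6% of the median smoothed peak of the other regions, so probe noise could give steep steps there. The end steps were divided by the highest probes instead, so these percentages are not on the same scale. In log2 the end steps of the runs in TOW were 4.29 to 8.58, above that noise, but the runs were chosen for steps of at least 3. Among the 10 tallest regions of each array, those on arms without a run had lower end steps. These were 14.1 to 30.5% of their height on TOW and 13.4 to 45.7% on MOD, so the runs did not taper as these regions did. The rule on noise was added after the first outcome, which had favoured ordinary ORC2 binding. Cloned DNA and ORC2 binding with steep ends cannot be told apart by this test.

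TOW stage 9/10 resembled MOD stage 10 more than it resembled TOW stage 10, the array of its own strain. A trend with input signal and GC content is argued against, since r in 10 kb bins was still 0.21 higher for MOD without both trends (0.67 against 0.47). Weaker enrichment on the whole TOW stage 10 array is argued against on the log2 scale by the mean TOW minus MOD of 0.066 at the shared domains; TOW over MOD was 1.03 there and 0.78 at the TOW stage 9/10 regions, 0.69 and 0.52 after division by the robust SD, and 1.47 and 3.34 with normexp, where TOW lay above MOD at those regions, so no single factor gives both. Probe noise on the TOW array stays open: corrected for reliability, r was 0.16 higher for MOD (0.78 against 0.62), but with normexp the gap was 0.07, below the 0.1 set as the bound. No biological explanation was tested, and a difference in the stage of the sorted chambers remains open.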

How the results depend on the processing

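The alternatives centred within input bins, on shared probes without bins and without domains, runs, scaffolds or input differences were chosen after seeing the data; the others were planned. Counts of regions are given in the order TOW stage 10, MOD stage 10 and, where it moved, TOW stage 9/10. They were 1778, 884 and 1171 as reported, 6066 and 3 with normexp, 1 and 1 with MA2C values, 5, 3 and 74 with a mirror share of 1%, 828, 238 and 570 at a fixed value of 1, and 1162 and 546 with smoothing over 500 bp. For TOW alone the count was 844 with the deposited value tables and 718 with probes well above background in both channels. The deposited tables hold the scanner log ratios uncentred, and the TOW stage 10 median was -0.05 before centring. The first of these counts thus moved with a small shift of the zero point. Thinning the denser array to the other spacing gave 603 regions there, since windows hold fewer probes. MA2C values cover fewer probes, so few windows reach 4. For the rest the cause was not tested.

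Of the shared regions, the share of MOD regions overlapping TOW stage 10 was 100%, 100% and 100% with normexp, MA2C values and a mirror share of 1%, where few MOD regions were left, 28.0% with the deposited tables and 24.0% with the probe filter, against 42.9%. The share of TOW stage 9/10 regions overlapping TOW stage 10 was 69.0% with normexp, 0% with MA2C values and the 1% mirror share, 8.10% with the deposited tables, 7.92% with the probe filter and 15.0% with GC centring, against 17.7%. The share of MOD regions overlapping TOW stage 9/10 was 0% with normexp, MA2C values and the 1% mirror share and 73.1% with the probe filter, against 62.3%.

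Correlations of TOW stage 10 with TOW stage 9/10 stayed positive. Against an r of 0.45 and a rho of 0.46, they were 0.32 and 0.25 with normexp, 0.47 and 0.49 with GC centring, 0.52 and 0.54 in 10 kb bins, 0.36 and 0.36 with centring within input bins and 0.49 and 0.48 on shared probes; rho was 0.49 with MA2C values and 0.50 with the probe filter. MOD had the higher r with TOW stage 9/10 under each of these settings, but not for probe values minus their 2 kb median (0.38 against 0.41 for TOW stage 10).

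The TOW minus MOD difference of 1.84 at 2L 1901181 to 1909301 was 2.61 with MA2C values and 3.29 after division by the robust SD, both in array SDs, 0.45 over 50 kb and 2.04 as a median. Its input difference of 0.49 was 0.25 over 50 kb and 0.17 with the probe filter. Domains of TOW stage 9/10 above random windows numbered 3 over 50 kb and 1 by the highest value, against 5. Regions differing by more than 1 numbered 226 (TOW higher) and 0 (MOD higher) with normexp, 28 and 436 with MA2C values and 77 and 454 with division by the robust SD, against 16 and 8; the last pair of settings is in array SDs, and TOW has the wider spread.

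Some single differences between TOW and MOD reversed. With normexp these were the 3L tip domain from 20861 (-0.056, and -0.11 for its input), 2RHet 2215741 (-0.21), U 2701751 (-0.060), 2R 12017051 (0.17), X 15962221 (0.011), 2R 5171151 (0.14), 2L 15111201 (0.11), 2L 22709071 (0.055), 3R 19025801 (0.015) and 3R 3931711 (0.10). The input difference at the 3L tip was -0.085 with the probe filter. With MA2C values the domain at 2R 18009191 (-0.33) and the regions at 2R 18009191 (-0.63), X 2681071 (-0.51), 3R 19857721 (-0.17) and X 2139191 (-0.056) reversed. After division by the robust SD the values were -0.0105 for the 2R domain, -0.0071 for the 3L tip domain, and -0.10 (2R 18009191), -0.43 (X 2681071) and -0.20 (3R 19857721) for the regions. Differences inside the range of random windows were not counted as reversed, but at 4 more domains they turned negative as well, to -1.10 (2L 9540111), -0.91 (2L 13410481), -1.45 (3L 2265951) and -1.45 (X 8360511), and with MA2C values to -1.41, -1.06, -1.35 and -1.78. Apart from the units of these scalings, the cause was not tested.

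No paired analysis was possible because each group has 1 array, and leaving out an array would leave a group empty. The planned results at amplicon loci, gene groups and promoters were not run under any setting, MA2C values were not used for TOW stage 9/10, and the bins without amplicon loci were replaced by bins without broad domains. Signal over background limits the TOW stage 10 array most, with 85.3% of ChIP signals well above background against 93.4% for MOD and 97.7% for TOW stage 9/10.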

Other observations

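The test of cytological bands below was chosen after the domains were seen. Input signal differed 4-fold or more between the strains at 7 short regions, 6 higher in TOW and 1 higher in MOD, which together cover 7.62 and 1.49 kb. The widest was on 2L from 22709691 to 22712471, where TOW input was 3.08 (log2) higher over 7 probes and only 2 of 7 probes had input well above background in MOD. On X from 12393111 to 12394011 the difference was 3.75, and on 3L from 88991 to 90001 it was 3.49 with 0 of 3 probes above background in MOD. The region higher in MOD lay on 2R from 10761641 to 10763131, with a difference of -5.89 and 1 of 4 probes above background in TOW. At 3L 45821 to 46821 neither channel of either strain had a probe well above background, so the input difference there is between background signals. ORC2 ratios of these regions are not read as binding.

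Probe values that stand out from their neighbours were shared between the stage 10 arrays. After each probe's 2 kb median was taken away, the remainders correlated with an r of 0.83 between TOW and MOD stage 10, 0.41 between TOW stage 10 and TOW stage 9/10 and 0.38 between MOD stage 10 and TOW stage 9/10, across probes, which are not independent replicates.

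One hypothesis is that the broad domains may be the amplified loci of follicle cells, which textbooks place at bands 7F, 22B, 30B, 34B, 62D and 66D. Each band was placed on its arm by linear interpolation of the band number, a rough scale. All 6 bands had a broad domain of their own within 2000 kb on the same arm, at distances of 333 to 1878 kb, and 0 of 10000 random placements of the 8 domains matched as many. The 2L domain seen in TOW only, from 1901181 to 1909301, was the nearest to 22B, at 469 kb. The placement is too coarse to show that any domain is the locus, and the domains and this test were chosen on the same data. The limit of 2000 kb was also set after the domains were seen and lies just above the largest distance. The 0 of 10000 is therefore no independent support.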
